A study of Mus musculus with 12 samples.

How the data were processed

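Gene expression was measured by RNA sequencing (TruSeq RNA libraries from total RNA) in RAW264.7 cells given RANKL with bacterial culture supernatant or with vehicle medium, at days 1, 3 and 5, with 2 libraries in each of 6 groups. Groups and replicate numbers were taken from the titles in the labels. Per the submitters' processing notes, the authors used TopHat2, SAMtools and DESeq2 with build mm9; versions, the annotation and the counting step are not given in the sources used here. The deposited values are log2 values per gene and library, 1 table for the whole series, per the file headers. Their form was worked out from the values: the lowest value is 3 and each value is log2 of a normalized count plus 8. After that offset was removed, 100% of the positive values in each library were whole multiples of 1 step, within 0.02 reads, so reads and relative size factors were recovered. The table had 24757 rows with 23764 Ensembl identifiers, and 993 repeated rows with equal values were dropped. Gene names came from the reference table by identifier for 23315 genes and from the file for the rest. The reference annotation is of a later build than the authors used, so no coordinates are given and it served for names and gene classes only. Reads from overlapping or antisense genes could not be told apart, since no strand setting is stated, and mitochondrial genes share reads with nuclear copies.

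Depth was 8071160 to 16781080 recovered reads per library. Replicates of a group differed by more than sampling noise: the chi-square per degree of freedom over genes with at least 10 reads in the pair was 3.94 and 4.93 in the groups of day 1 and between 495 and 708 in those of days 3 and 5.

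The test, the samples, the filter, the gene lists and the rule for named genes were fixed before the data were examined. Genes with a mean normalized count of at least 10 in at least 1 of 6 groups were kept (14715 genes). A limma model (limma 3.58.1 in R 4.3.3, trended prior) with 1 mean per group was fitted to log2(normalized count + 1) over 12 libraries, with 6 residual degrees of freedom and no block, and p-values were adjusted by the Benjamini-Hochberg method over genes. A fold change on this scale understates changes of genes with low counts. The difference of the treatment effect between days was tested with an F test over 2 contrasts. Of 27 gene lists, those with at least 5 tested members were compared with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. No list call at any treatment day, nor for either vehicle comparison, held at an adjusted p of 0.05 with an estimated correlation. Over 12 libraries that correlation came from residuals to which replicates of days 3 and 5 added most. It was the same in each comparison, at 0.96 for the cell cycle list and 0.48 for the inflammatory list. A list that did not hold there is not shown to be unchanged.

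Named genes were, per treatment comparison, the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a normalized count of at least 50 in the higher group and each treated library beyond each vehicle library, 6 each for the vehicle comparisons and the 6 smallest p for the difference between days, then up to 4 members with the smallest p over 12 libraries of each list described, and 9 genes named in every comparison. As no gene passed over 12 libraries, the first part was applied to the 8-library fit and to its libraries, which was decided after seeing the data. The 8 libraries are those with over 60% of reads on nuclear protein-coding genes. Identifiers without a symbol were not named, and 2 genes that the rule takes are not reported here.

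The alternatives fixed in advance were a replicate block, each library left out, no filter, quantile normalization, pseudocounts of 0.5 and 5, only the 4 libraries compared and, for lists, an estimated correlation and fry. Those added after seeing the data were the fit without the 4 low-mRNA libraries, a term for them, such a term by day, the deposited log2 values as they are and limma-voom on recovered reads with and without these libraries. A count test planned for recovered reads was not run, because the deposited unit is a log2 value, and limma-voom took its place. The model was tested on simulated counts with genes changed by 1 or 2 log2 units. The 12-library fit recovered 0 of them, and the 8-library fit recovered part of them at each day with 0 false calls. The simulation gave every library the spread of day 1, as the 8-library fit assumes. So it cannot tell whether real calls at days 3 and 5, with 1 library per arm, are false. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.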

Results

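RAW264.7 cells, an immortalized mouse line of monocyte and macrophage character, were stimulated with RANKL, the cytokine that drives such cells toward osteoclasts. The cells received either culture supernatant of the gut bacterium Lactobacillus reuteri (treatment) or MEM-alpha medium (vehicle). RNA was sequenced from total RNA at days 1, 3 and 5, with 2 libraries per arm and day, 12 libraries in all. The labels number the libraries of a group but do not say whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Each library held between 8071160 and 16781080 reads on genes, recovered from the deposited values.

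The libraries fell into 2 kinds by composition. In replicate 2 of day 3 and of day 5, in both arms, 38.1% to 48.8% of reads lay on nuclear protein-coding genes, against 85.2% to 87.6% in the other 8 libraries. The nuclear RNA Malat1 took 8.15% to 13.97% of reads in those 4 libraries and 0.218% to 0.489% in the others, and mitochondrial genes took 25.7% to 30.6% against 3.64% to 5.97%. The 4 libraries, called low-mRNA libraries from here on, also held fewer reads, at most 10724569, against at least 13812078 in the others. The first principal component separated them and carried 81.4% of the variance. Because every group of days 3 and 5 held 1 library of each kind, treatment values at those days are given for the pair of libraries with number 1, and for most genes and lists also for the low-mRNA pair.

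**Figure D1:**
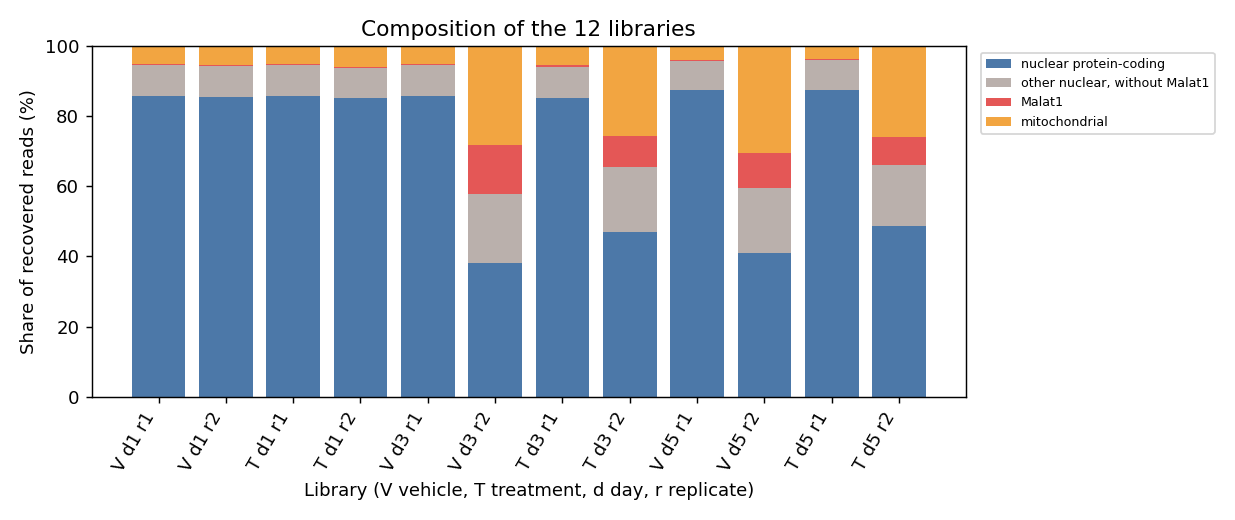
Share of recovered reads (percent, vertical axis) on 4 classes of gene in each of the 12 libraries (horizontal axis), as stacked bars from 0 to 100. Replicate 2 of days 3 and 5 carried 38.1% to 48.8% nuclear protein-coding reads in both arms, and the other 8 libraries 85.2% to 87.6%.

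With all 12 libraries in limma, no gene passed a Benjamini-Hochberg adjusted p of 0.05 for treatment at day 1, 3 or 5, for vehicle day 3 or day 5 against day 1, or for a difference of the treatment effect between days. At an unadjusted p under 0.05 the counts were 19, 43, 51, 288, 207 and 3 of 14715 genes in that order, with 736 given by chance in each of the first 5, and limma-voom on recovered reads from all 12 libraries also called 0 in each. Tested on simulated data, this fit recovered 0 of the genes changed by 1 or by 2 log2 units, so a count of 0 does not show that genes stayed the same. Genes are therefore described from the same limma model fitted to the 8 libraries that are not low-mRNA libraries, a choice made after seeing the data, and "rose" and "fell" refer to an adjusted p under 0.05 in that 8-library fit. In it the spread comes from the 2 groups of day 1 alone, with 2 residual degrees of freedom, and the lone libraries of days 3 and 5 are assumed to vary as those of day 1 did. A 12-library fit with a term by day for the low-mRNA libraries, also chosen after seeing the data, called genes in each of the first 5 comparisons. Its counts, given with the other processing choices below, were lower than those of the 8-library fit in each.

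At day 1 the treated cells carried more transcript of inflammatory mediators. Acod1, the enzyme that makes itaconate in activated macrophages, stood at 1762 ± 25.5 normalized counts (SD, n = 2) under treatment and 202 ± 23.4 in vehicle, a log2 difference of 3.12 (SE 0.10, limma adjusted p = 0.00406). The chemokine gene Cxcl2 rose by 3.81 log2 units (SE 0.61), from 48.9 ± 41.2 to 567 ± 44.9 (SD, n = 2), and the acute-phase gene Saa3 rose by 3.81 (SE 0.40), from 4.75 ± 2.90 to 74.2 ± 0.85. Il1rn, which encodes the interleukin 1 receptor antagonist, rose by 2.05, and Ptges, a prostaglandin E synthase, by 2.15. Mmp14, Ccrl2 and Slpi rose by 2.58, 2.52 and 2.51. Among genes that fell, Adm went from 98.1 ± 9.12 to 36.0 ± 2.26 (SD, n = 2) and Txnip, which binds and inhibits thioredoxin, from 3090 ± 129 to 1276 ± 3.89. Lower log2 values were also called for Nanos1 (-1.40), Bmf (-1.29), Gm15441 (-1.28), Hspa1b (-1.27), St6gal1 (-1.10) and Kbtbd11 (-1.09). Hspa1b shares reads with its near-identical paralog Hspa1a, so its count is uncertain.

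By gene list, 14 of 22 tested genes of the inflammatory TLR and NF-kB response rose at day 1, none fell and 8 did not pass, and 16 rose when adjusted over the list alone. The list was higher over all 12 libraries by camera with a preset correlation (adjusted p = 2.09e-41, median log2 difference 0.93), with an adjusted p = 0.0917 with an estimated correlation. Of 29 interferon response genes 21 rose, none fell and 8 did not pass, 26 rose adjusted over the list alone, and all 29 were higher in the mean. Rsad2, the antiviral protein viperin, rose from 20.2 ± 0.64 to 86.2 ± 13.0 normalized counts (SD, n = 2), and Bst2 and Oas1a rose by 0.72 and 0.66 log2 units, while Usp18 differed by 1.45 without passing (adjusted p = 0.0703). The camera adjusted p of this list was 7.92e-22, and its adjusted p = 0.447 with an estimated correlation. In the amino acid and integrated stress response 10 of 23 genes rose and none fell, 15 rose adjusted over the list alone, among them Ddit3, a stress-induced transcription factor, by 1.34, the cystine transporter gene Slc7a11 by 1.21 and Atf3 by 1.13 log2 units. Chac1 differed by 1.11 (adjusted p = 0.0630). The list's camera adjusted p was 8.56e-12, and its adjusted p = 0.447 with an estimated correlation.

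Of 22 tested osteoclast effector genes 7 rose at day 1, none fell and 15 did not pass, 16 were higher and 6 lower in the mean, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 1.62e-06, adjusted p = 0.447 with an estimated correlation). Ctsk, the collagen-degrading protease cathepsin K, rose from 170 ± 0.0 to 301 ± 22.1 normalized counts (SD, n = 2), Src by 0.96, Car2 by 0.94 and the chloride exchanger gene Clcn7 by 0.63 log2 units. Acp5, the osteoclast enzyme TRAP, stood at 24.9 ± 1.27 against 16.4 ± 6.01 (SD, n = 2) and did not pass. Nor did Mmp9 (0.23 log2 units), Nfatc1 (-0.22), Dcstamp (-0.02) or Tnfrsf11a (-0.25). Irf8, which is on the list of negative regulators of osteoclastogenesis, differed by 0.37 without passing. Cell cycle genes were lower: 12 of 34 fell, none rose and 22 did not pass, and 23 fell adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.933 with an estimated correlation). Among them were Ccne2 (-0.85), Ccne1 (-0.68), Cdc6 (-0.59) and Tyms (-0.48). In all, 844 genes changed at day 1 in the 8-library fit, 459 up and 385 down, and 820 in a fit of the 4 day 1 libraries alone, 810 of them shared. The counts rest on all 4 day 1 libraries. Without vehicle replicate 1 or 2, or treatment replicate 1 or 2, of day 1 the 8-library fit had 1 residual degree of freedom and called 0 genes for treatment at each day.

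At day 3 Acod1 stood at 490.7 and 398.4 normalized counts in the treated libraries and at 36.7 and 17.6 in vehicle, a log2 difference of 3.70 in the pair without low-mRNA libraries (SE 0.14, limma adjusted p = 0.00432) and 4.42 in the low-mRNA pair. Ptgs2, the inducible cyclooxygenase, rose by 3.47 log2 units, with 0.89 in the low-mRNA pair. Il13ra2, a decoy interleukin receptor, rose by 3.22 (2.86 in the low-mRNA pair), the macrophage elastase gene Mmp12 by 2.62 (1.52) and Clec4e, a receptor for microbial and damage-associated lipids, by 2.10 (2.17). Ikbke rose by 1.99 (2.06), the complement gene C3 by 1.91 (3.07) and Klra2, a member of a family of similar genes whose reads may be shared, by 1.86 (1.20). Across all 14715 genes the treatment differences of the 2 pairs correlated at only 0.14 at day 3, against 0.43 at day 1 and 0.21 at day 5. The median of all genes was higher under treatment in the low-mRNA pair of day 3, which favours agreement for genes that were higher. All 17 genes called at day 3 in the 8-library fit were higher under treatment, and all 17 were also higher in the low-mRNA pair. Without any 1 day 1 library the count was 0.

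Of the 22 inflammatory genes 2 rose at day 3 and 20 did not pass, and 15 rose adjusted over the list alone. The list median was 0.79 in the first pair and 1.19 in the low-mRNA pair (camera over 12 libraries, adjusted p = 2.35e-23, and adjusted p = 0.340 with an estimated correlation). Cxcl2 and Ptges differed by 2.74 and 1.60 log2 units in the first pair without passing (5.09 and 2.88 in the low-mRNA pair). Saa3 stood at 14.9 and 47.2 normalized counts under treatment and at 0 in both vehicle libraries. Of 29 interferon genes 2 rose and 27 did not pass, and 24 rose adjusted over the list alone, with medians of 1.07 and 0.87 in the 2 pairs (camera adjusted p = 1.28e-07, adjusted p = 0.999 with an estimated correlation). Isg15, Rsad2, Bst2 and Oas1a differed by 2.38, 2.09, 0.86 and 0.75 in the first pair and by 4.62, 3.39, 1.39 and 1.31 in the low-mRNA pair, and none of the 4 passed. In the NRF2 and oxidative stress list 1 of 16 genes, Slc7a11, rose (1.20 log2 units), and 6 rose adjusted over the list alone. All 16 were higher in both pairs, with medians of 0.27 and 0.97 (camera adjusted p = 3.67e-05, adjusted p = 0.999 with an estimated correlation). The ferritin heavy chain gene Fth1 differed by 0.65 and Prdx1 by 0.64 without passing, and Ftl1 by 0.20 (1.66, 1.45 and 1.22 in the low-mRNA pair). In the macrophage identity list Cx3cr1 rose by 0.68 (0.81 in the low-mRNA pair) and the other 21 genes did not pass, with 10 rising adjusted over the list alone. The medians were 0.16 and 0.95 (camera adjusted p = 0.00207, adjusted p = 0.999 with an estimated correlation). Cybb, Cd14 and Lyz2 differed by 0.92, 0.95 and 0.56 in the first pair and by 1.14, 1.74 and 1.48 in the low-mRNA pair. The amino acid and integrated stress response list was higher too, with medians of 0.26 and 1.05 (camera over 12 libraries, adjusted p = 2.63e-07, adjusted p = 0.999 with an estimated correlation). The low-mRNA vehicle library of day 3 had 38.1% nuclear protein-coding reads and its treated partner 47.1%. The median of all genes over 12 libraries was 0.23 log2 units higher under treatment at that day, against -0.01 in the 8-library fit. In the low-mRNA pair the inflammatory list median of 1.19 was 0.73 relative to all genes, so the values of that pair carried a general shift.

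None of the osteoclast genes named here passed at day 3, nor did the negative regulator Irf8. Acp5 stood at 1068 and 675 normalized counts in vehicle and at 742 and 814 under treatment, and Ctsk at 2086 and 581 against 1866 and 1414. Mmp9, Nfatc1, Dcstamp, Tnfrsf11a and Irf8 differed by -0.20, -0.22, -0.39, -0.08 and -0.06 in the first pair. In the low-mRNA pair they differed by 1.36, 0.36, 0.73, 0.11 and 0.50. The median of all genes was higher under treatment in that pair too, and Nfatc1 and Tnfrsf11a lay below it.

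At day 5 Ptgs2 stood at 281.7 and 42.7 normalized counts in the treated libraries and at 15.6 and 1.4 in vehicle, a log2 difference of 4.09 (SE 0.24, limma adjusted p = 0.00832) and of 4.18 in the low-mRNA pair. Tnfrsf9, a costimulatory receptor of the TNF receptor family, rose by 5.25 (3.02 in the low-mRNA pair), the placental growth factor gene Pgf by 4.78 (4.04), Saa3 by 4.55 (5.20), Adm by 4.36 (1.88) and Pdpn by 3.86 (2.79). Ambp and Ifi44l rose by 3.22 and 2.79 in the first pair, but differed by -1.94 and 0.0 in the low-mRNA pair. Among the named genes the largest fall was that of Ocstamp, which is needed for the fusion of osteoclast precursors: it stood at 3.7 against 54.3 normalized counts in the first pair (-3.57, SE 0.19, limma adjusted p = 0.00806) and at 212.1 against 329.2 in the low-mRNA pair (-0.63). Fgd2 (-1.87) and Hist1h2ac (-1.87) fell as well, with -0.78 and -1.90 in the low-mRNA pair. Odf3l1 (-2.39), Nme4 (-1.79), Gstt1 (-1.77), Gpr162 (-1.73) and Tmem176a (-1.71) fell in the first pair, with 0.48, 0.12, -0.18, 0.54 and -0.14 in the low-mRNA pair. In all 855 genes changed, 374 up and 481 down, and 538 of the 855 (62.9%) had the same direction in the low-mRNA pair, where chance gives about 50%. Without any 1 day 1 library the count was 0.

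Of the 22 inflammatory genes 9 rose at day 5, 2 fell and 11 did not pass (13 and 3 adjusted over the list alone), among them Acod1 by 2.73 and Ier3 by 2.43 log2 units, and Cxcl2 differed by 2.20 without passing. The medians were 1.10 and 1.25 in the 2 pairs (camera adjusted p = 3.28e-36, adjusted p = 0.0759 with an estimated correlation). The interferon list was higher as well, with medians of 0.98 and 0.36 (camera over 12 libraries, adjusted p = 2.29e-06, adjusted p = 0.828 with an estimated correlation). In the glycolysis and hypoxia list 16 of 25 genes rose and none fell, and 23 rose adjusted over the list alone. The medians were 0.63 and 0.81 (camera adjusted p = 1.36e-10, adjusted p = 0.828 with an estimated correlation). Vegfa rose by 1.53, Ankrd37 by 1.07 and the hexokinase gene Hk2 by 0.90, and P4ha2, at 21.1 against 0.9 normalized counts in the first pair and at 0 in both low-mRNA libraries, did not pass. Of 23 genes of the amino acid and integrated stress response 10 rose and none fell, and 18 rose adjusted over the list alone. Slc7a11 rose by 1.60 and Slc6a9 by 1.56 log2 units, while Trib3 (0.66) and Pck2 (0.50) did not pass (for the list, camera adjusted p = 5.49e-16, adjusted p = 0.458 with an estimated correlation). In the unfolded protein response 9 of 16 genes rose, 14 rose and 1 fell adjusted over the list alone, including the chaperone genes Hsp90b1 (0.71), Calr (0.71), Manf (0.68) and Dnajc3 (0.57), with medians of 0.58 and 0.65 (camera adjusted p = 3.91e-05, adjusted p = 0.828 with an estimated correlation). Of 34 cell cycle genes 16 fell and none rose, and 25 fell and 1 rose adjusted over the list alone, with medians of -0.48 and -0.41 (camera adjusted p = 1.02e-04, adjusted p = 0.828 with an estimated correlation). At day 3 this list went the other way, with 31 of 34 genes higher under treatment in each pair. Its medians there were 0.22 in the first pair and 0.47 in the low-mRNA pair (camera over 12 libraries, adjusted p = 0.995). The median of all genes was higher in that low-mRNA pair too. At day 5 Aurka (-0.64) and Tyms (-0.57) fell, and Cenpf (-0.68) and Cenpe (-0.44) did not pass. Replication-dependent histones, a check on RNA selection, were lower too: 2 of 12 fell, none rose and 10 did not pass, and 5 fell adjusted over the list alone. Over 12 libraries 11 of the 12 were lower in the mean, with medians of -1.08 and -0.98 in the 2 pairs (camera adjusted p = 1.36e-10, adjusted p = 0.0759 with an estimated correlation).

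**Figure D2:**
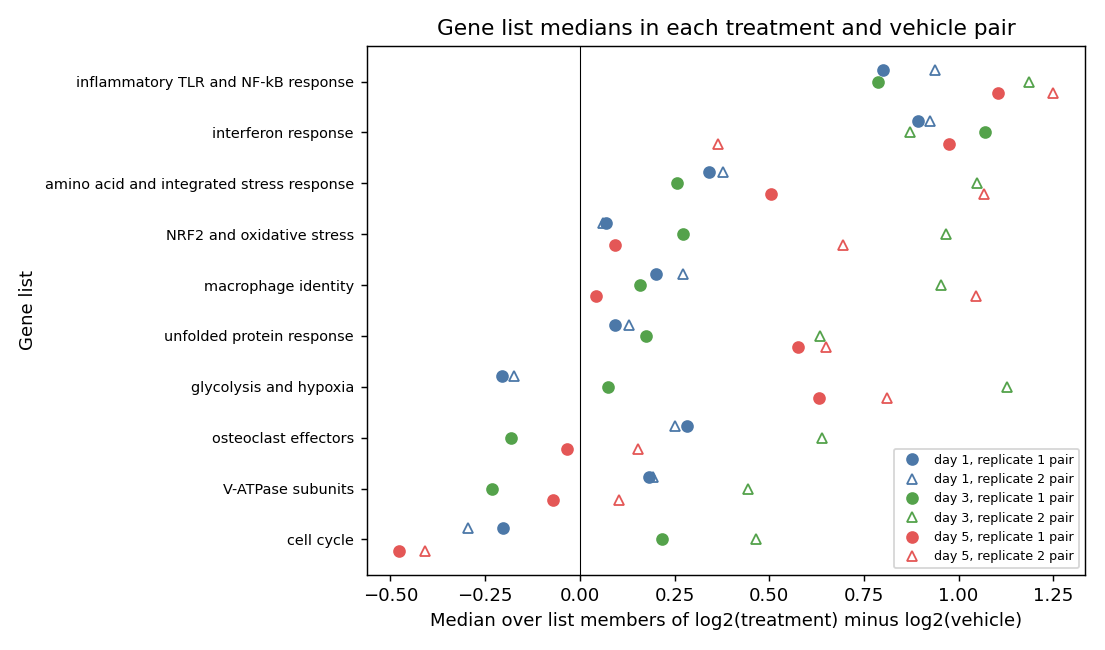
Median over the tested members of 10 gene lists (vertical axis) of the log2 difference between the treated and the vehicle library of the same day and number (horizontal axis), in blue for day 1, green for day 3 and red for day 5, with filled circles for the replicate 1 pairs and open triangles for the replicate 2 pairs, which are low-mRNA pairs at days 3 and 5. The inflammatory list lay above 0 in all 6 pairs, from 0.79 to 1.25.

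Among osteoclast genes, Tnfrsf11a, the RANK receptor gene, fell at day 5 (-0.75, with -0.44 in the low-mRNA pair, limma adjusted p = 0.0207). Acp5, Ctsk, Mmp9, Nfatc1 and Dcstamp differed by -0.74, -0.09, 0.27, -0.30 and -0.06 and did not pass. The negative regulator Irf8 differed by 0.48 and did not pass either. Ffar4, a fatty acid receptor gene, was under the filter on low values and was not tested. The levels of Acp5 and Ctsk at day 5 depended on the library: Acp5 stood at 35.9 in vehicle and 21.1 under treatment in replicate 1, and at 1231 and 772 in the low-mRNA replicate 2, and Ctsk at 299.1 and 280.8 against 6680 and 7164.

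**Figure D3:**
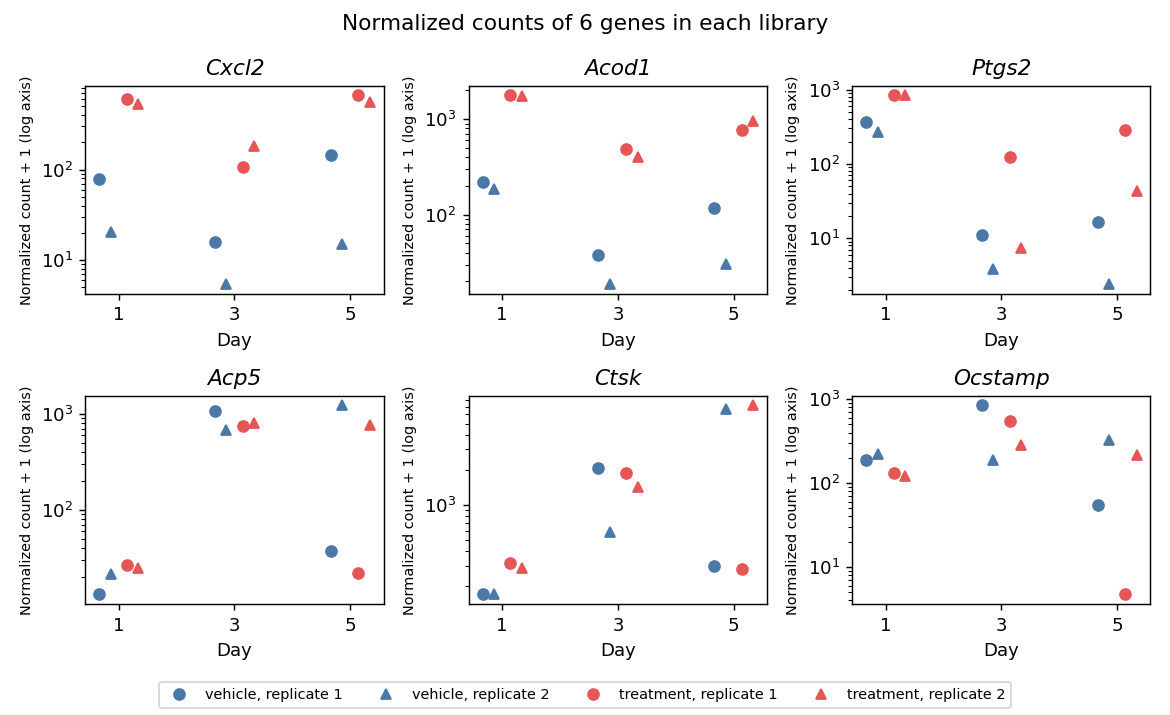
Normalized counts plus 1 (log axis) of 6 genes in each library at days 1, 3 and 5, in blue for vehicle and red for treatment, with circles for replicate 1 and triangles for replicate 2. Acod1 was higher in each treated library than in both vehicle libraries of its day, and Acp5 at day 5 stood at 35.9 and 21.1 in replicate 1 and at 1231 and 772 in replicate 2.

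No gene passed the test for a treatment effect that differed between days over 12 libraries by limma. Hcar2, Ier3 and Flvcr2 had the 3 smallest unadjusted p, each under 0.05, followed by Runx3, Gsta1 and Gm26837. In the 8-library fit 15 genes passed. Adm differed under treatment by -1.42, -1.50 and 4.36 log2 units at days 1, 3 and 5, Bnip3 by -0.47, 0.17 and 1.10, Mycn by -1.04, -0.20 and 0.90 and Kbtbd11 by -1.09, -0.33 and 0.85. C3 differed by 0.93, 1.91 and 0.16, and Zfhx4 by -0.09, -0.26 and 1.05. In the low-mRNA pairs of days 3 and 5 the differences were 2.05 and 1.88 for Adm, 2.48 and 1.90 for Bnip3, 0.70 and -0.25 for Mycn, -0.01 and -1.24 for Kbtbd11, 3.07 and 2.96 for C3 and -0.33 and -0.85 for Zfhx4. So the course over days differed between the pairs, and at day 5 Mycn, Kbtbd11 and Zfhx4 had opposite signs in them. The limma adjusted p of each of these 6 was 0.0427.

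In vehicle cells Acp5 rose from day 1 to day 3 in replicate 1, by 5.99 log2 units (SE 0.33, limma adjusted p = 0.00120), from 16.4 ± 6.01 (SD, n = 2) at day 1 to 1068 normalized counts, and the low-mRNA library stood at 675. Prdm1, Slc9b2, Coq8a, Matk and the V-ATPase subunit gene Atp6v0d2 rose by 5.56, 5.10, 4.03, 4.02 and 3.95, and Ctsk, Mmp9 and Nfatc1, the main transcription factor of osteoclast formation, by 3.61, 2.86 and 2.04. The low-mRNA library held 930.4 normalized counts of Nfatc1, below the day 1 mean of 1515, and 682.0 of Tnfrsf11a, below its day 1 mean of 2327. Of 22 osteoclast effectors 11 rose and none fell, and 12 rose and 2 fell adjusted over the list alone (camera over 12 libraries, adjusted p = 2.58e-07, adjusted p = 0.713 with an estimated correlation), with Siglec15 at 2.98. Treml4 (-5.67), Ptgs2 (-4.82), Aqp9 (-4.15), Adh7 (-3.59) and Il13ra2 (-3.49) fell. Trem3 also fell, from 50.8 ± 3.18 normalized counts (SD, n = 2) at day 1 to 0 in both day 3 libraries. All 23 genes of the amino acid and integrated stress response fell, also adjusted over the list alone, with Chac1 at -3.41, Trib3 at -3.21, Slc7a11 at -2.30 and Pck2 at -2.12 (camera adjusted p = 9.75e-11, adjusted p = 0.713 with an estimated correlation). Of 25 glycolysis and hypoxia genes 23 fell and 2 did not pass, and 24 fell and 1 rose adjusted over the list alone. The log2 differences were -1.78 for Vegfa, -1.69 for Bnip3, -1.30 for Slc16a3 and -0.89 for Hk2 (for the list, camera adjusted p = 3.07e-08, adjusted p = 0.733 with an estimated correlation). Tnfrsf11a rose by 0.53 in replicate 1, and Dcstamp (-0.04) and Irf8 (-0.69) did not pass. In all 2898 genes changed, 1426 up and 1472 down. Without vehicle replicate 1 or 2 of day 1 the count was 0 or 69, and without treatment replicate 1 or 2 of day 1 it was 1412 or 1427. Over 12 libraries the median of all genes shifted by -0.83 log2 units at day 3 and by -0.59 at day 5, against 0.04 and -0.0033 in the 8-library fit.

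In the vehicle cells of replicate 1 at day 5, against day 1, Selenop, F630028O10Rik, Cmah, March1, Timp2 and Ms4a7 rose by 5.26, 4.54, 4.54, 4.34, 4.01 and 3.82 log2 units. With the low-mRNA library, the 12-library differences were 5.19, 2.50, 3.20, 2.30, 4.16 and 2.80 in that order. In the macrophage identity list 19 of 22 genes rose, 2 fell and 1 did not pass, the same numbers adjusted over the list alone. The median was 1.04 in the 8-library fit. Over 12 libraries the list median was -0.17, where that of all genes was -0.59 (camera adjusted p = 0.0679, adjusted p = 0.947 with an estimated correlation). Ptgs2 (-4.24), Adm (-4.14), Mgarp (-3.30), mt-Tt (-3.11) and Dmpk (-2.66) fell, but mt-Tt stood at 117.3 normalized counts in the low-mRNA library, above its day 1 mean of 55.6. Of 22 osteoclast effectors 9 rose, 3 fell and 10 did not pass, and 11 rose and 3 fell adjusted over the list alone (camera over 12 libraries, adjusted p = 2.83e-09, adjusted p = 0.438 with an estimated correlation), with Tspan10, Mmp9 and Atp6v0d2 up by 3.80, 2.07 and 1.44 and Itgb3 at 1.47 without passing. Ctsk rose by 0.81 and Irf8 by 0.95, Nfatc1 (-0.92), Dcstamp (-0.84) and Tnfrsf11a (-0.30) fell, and Acp5 differed by 1.13 without passing. With the low-mRNA library, the 12-library differences of Ctsk, Irf8, Nfatc1, Dcstamp, Tnfrsf11a and Acp5 were 3.05, 0.50, -0.89, -0.42, -1.21 and 3.66. Acp5 stood at 1231 normalized counts in that library and at 35.9 in replicate 1. Of 34 cell cycle genes 31 fell and 3 did not pass, 32 fell adjusted over the list alone, with Cenpe, Cenpf, Ccne2 and Tyms at -0.69, -0.67, -0.67 and -0.51 (camera adjusted p = 2.73e-07, adjusted p = 0.947 with an estimated correlation). Of 25 glycolysis and hypoxia genes 23 fell and 24 fell adjusted over the list alone, with Bnip3, Slc16a3, Tpi1 and Hk2 at -2.27, -1.65, -1.19 and -0.74 (camera adjusted p = 3.43e-09, adjusted p = 0.901 with an estimated correlation). In all 4330 genes changed, 2122 up and 2208 down. Without vehicle replicate 1 or 2 of day 1 the count was 880 or 715, and without treatment replicate 1 or 2 of day 1 it was 2608 or 2610. Mitochondrial genes took 30.6% of reads in the low-mRNA vehicle library of day 5 and 4.02% in replicate 1.

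Lists of genes that changed over time in vehicle could not be formed from all 12 libraries, since no gene passed. In the 8-library fit each list was tested at the day whose libraries it did not compare. The spread behind both the list calls and the tests came from the day 1 libraries, so list and test were not independent. The 424 genes lower at day 3 than at day 1 were higher under treatment at day 5, with 340 higher and 84 lower and a median of 0.56 (camera adjusted p = 2.47e-33, adjusted p = 0.207 with an estimated correlation), and the 232 genes higher at day 3 were lower under treatment at day 5, with 167 lower and 61 higher and a median of -0.38 (camera adjusted p = 0.00768, adjusted p = 0.214 with an estimated correlation). In the low-mRNA pair the medians of these lists were 0.93 and -0.07. The 941 genes higher at day 5 than at day 3 were higher under treatment at day 1 (median 0.27, camera adjusted p = 1.82e-21, adjusted p = 0.207 with an estimated correlation), while the 417 genes lower at day 5 had a median of -0.10 (adjusted p = 0.467). At day 3 the 341 genes lower at day 5 than at day 1 had a median of 0.12 (camera adjusted p = 5.85e-05, adjusted p = 0.244 with an estimated correlation) and the 608 higher genes a median of 0.05 (adjusted p = 0.0853). In the low-mRNA pair of day 3 the medians of these lists were 0.67 and 0.63, and the median of all genes was higher under treatment there as well.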

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

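The spread across genes, its correlation between arms and the tests of the low-mRNA state, of a day 1 culture, of the low-mRNA libraries for the inflammatory list and of the treatment itself were chosen after the result was seen; the tests of genomic DNA, nuclear RNA, exchanged days and scaling were written before it.

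Camera tests of the difference between days over 12 libraries picked out 18 list differences. None held with an estimated correlation, where the lowest adjusted p was 0.101. In the 8-library fit, too, none held with an estimated correlation. Values are mean log2 differences between treatment effects. From day 1 to day 3 they were -0.26 for osteoclast effectors, -0.074 for V-ATPase subunits, 0.86 for glycolysis and hypoxia and -0.46 for replication-dependent histones. From day 1 to day 5 they were -0.48 for osteoclast effectors, -0.14 for V-ATPase subunits, 0.36 for the inflammatory list, -0.30 for the interferon list, 1.07 for glycolysis and hypoxia, 0.40 for the amino acid and integrated stress response, 0.51 for the unfolded protein response and -1.19 for histones. From day 3 to day 5 they were 0.21 for the inflammatory list, -0.76 for the cell cycle, 0.22 for glycolysis and hypoxia, 0.16 for the amino acid and integrated stress response, 0.21 for the unfolded protein response and -0.73 for histones. In the 8-library fit 5 of the 18 did not pass: the inflammatory list from day 1 to day 5 (median -0.39, camera adjusted p = 0.240) and from day 3 to day 5 (-0.047, adjusted p = 0.873), the interferon list from day 1 to day 5 (0.064, adjusted p = 0.594), and histones from day 1 to day 3 (-0.14, adjusted p = 0.630) and from day 3 to day 5 (-1.04, adjusted p = 0.0589).

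The first pattern is the composition of the 4 low-mRNA libraries. A few abundant RNAs taking the reads is argued against as the whole cause, since the SD across protein-coding genes of the difference between replicates was at least 4.77 times that at day 1 and these differences correlated between the arms at 0.872 at day 3 and 0.871 at day 5. A loss of cytoplasmic relative to nuclear RNA is consistent with the other nuclear RNAs tested, whose median lay at least 2.56 log2 units above that of protein-coding genes in all 4 groups, although Tug1, 1 of the 4, went the other way (-3.65 to -1.79). Reads from genomic DNA cannot be told apart from this: at an equal 4992475 nuclear reads, the low-mRNA library detected fewer genes in 1 of the 4 groups and more in the other 3. Replication-dependent histones, the check on RNA selection, had 12-library medians of 0.76 and 0.47 in vehicle at days 3 and 5 against day 1. The medians of all genes there were -0.83 and -0.59. Without the low-mRNA libraries the histone medians were 0.08 and -0.06. A difference in RNA selection was not tested and stays open. No biological explanation was tested, as each group holds both kinds of library.

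The second pattern is the split of osteoclast effectors at day 5, where the list median in replicate 2 lay 2.21 log2 units above replicate 1 in vehicle and 1.93 under treatment, relative to all genes. The low-mRNA state alone is argued against as the whole cause, since the same difference at day 3 was smaller by 2.21 and 1.28 log2 units (smallest 1.28). An exchange of days 3 and 5 in replicate 1 would turn the day 5 minus day 3 differences of the replicates against each other, but they correlated at 0.212 and 0.351 across genes, which are not independent. That replicate 1 of day 5 was a day 1 culture stays open: its spread was at least 1.84 times that between day 1 replicates, but separate cultures may vary by more than those. A different course of the cultures stays open as well, and no biological explanation was tested.

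The third pattern is the inflammatory list, higher under treatment at each day by camera with a preset correlation, with adjusted p = 0.0917, 0.340 and 0.0759 at days 1, 3 and 5 with an estimated correlation. The low-mRNA libraries are argued against, as the lowest median in the 4 pairs without them was 0.79 above that of all genes. Scaling is argued against as well, since the list lay at the percentile of 100 among 10000 random lists of matched mean value in the lowest of the pairs. Medians above 0 in 6 of 6 pairs are the pattern itself and do not test an effect of the supernatant, which stays open.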

How the results depend on the processing

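The fits without the low-mRNA libraries, with terms for them, with the deposited log2 values and with limma-voom were chosen after seeing the data. Over 12 libraries all 6 counts of changed genes were 0 under the replicate block, no filter, quantile normalization, both pseudocounts, the deposited log2 values, limma-voom and each library left out. The replicate numbers were not taken to pair the samples in the 12-library fit. Vehicle and treated deviations correlated at 0.070 at day 1, but at 0.90 at day 3 and 0.90 at day 5. So at days 3 and 5 the replicates differed much alike in both arms, and this adds to the spread of that fit. With the replicate block the counts of changed genes stayed at 0 and the lists moved numbered 10, 11, 11 and 11. That block sets 1 difference for all days, so it cannot test a pairing present at days 3 and 5 alone. The low-mRNA term by day, given below, sets a separate difference for each of these days. The fit without the low-mRNA libraries gave 844 (treatment vs vehicle, day 1: genes changed), 17 (treatment vs vehicle, day 3: genes changed), 855 (treatment vs vehicle, day 5: genes changed), 2898 (vehicle day 3 vs day 1: genes changed), 4330 (vehicle day 5 vs day 1: genes changed), 15 (treatment effect differs between days: genes changed). A fit with a term for them gave 1 (treatment vs vehicle, day 3: genes changed), 12 (treatment vs vehicle, day 5: genes changed), 34 (vehicle day 3 vs day 1: genes changed), 53 (vehicle day 5 vs day 1: genes changed). A fit with such a term by day gave 6 (treatment vs vehicle, day 1: genes changed), 10 (treatment vs vehicle, day 3: genes changed), 60 (treatment vs vehicle, day 5: genes changed), 423 (vehicle day 3 vs day 1: genes changed), 431 (vehicle day 5 vs day 1: genes changed). Limma-voom without them gave 2007 (treatment vs vehicle, day 1: genes changed), 341 (treatment vs vehicle, day 3: genes changed), 1960 (treatment vs vehicle, day 5: genes changed), 4234 (vehicle day 3 vs day 1: genes changed), 5279 (vehicle day 5 vs day 1: genes changed), 973 (treatment effect differs between days: genes changed). A fit of only the 4 libraries compared gave 820 (treatment vs vehicle, day 1: genes changed). These fits have fewer samples or a modelled spread. Of 23 lists, camera counts were 10 (gene lists moved by treatment, day 1), 11 (gene lists moved by treatment, day 3), 11 (gene lists moved by treatment, day 5), 10 (gene lists moved, vehicle day 5 vs day 1), and 0 in each with an estimated correlation and 0 with fry. Without a filter these were 4 (gene lists moved by treatment, day 1), 5 (gene lists moved by treatment, day 3). Without the low-mRNA libraries these were 17 (gene lists moved, vehicle day 5 vs day 1). With a term by day these were 16 (gene lists moved by treatment, day 1), 17 (gene lists moved, vehicle day 5 vs day 1). Leaving out 1 library gave ranges of 8 to 10 (gene lists moved by treatment, day 1), 3 to 12 (gene lists moved by treatment, day 3), 5 to 11 (gene lists moved by treatment, day 5), 9 to 15 (gene lists moved, vehicle day 5 vs day 1). Time course genes under treatment gave 0 lists over 12 libraries, where none could be formed, and 4 without the low-mRNA libraries, 4 with a term for them and 4 with such a term by day. The cause was not tested for the list counts. Of 172 gene and comparison pairs 0 passed over 12 libraries. Most passed without the low-mRNA libraries, among them Tnfrsf11a, vehicle day 3 vs day 1, which also turned direction. Many of these genes were named because they passed in that same fit, so their passing there is no test of them. With all 12 libraries and a low-mRNA term, 19 pairs passed in the same direction, and 63 did with such a term by day. Log2 values that turned direction follow, and the cause was not tested. Quantile normalization gave 0.00651 (Dcstamp, treatment vs vehicle, day 1), -0.0899 (Nfatc1, treatment vs vehicle, day 3), -0.0476 (Dcstamp, treatment vs vehicle, day 3), -0.13 (Tnfrsf11a, treatment vs vehicle, day 3), -0.00806 (Irf8, treatment vs vehicle, day 3), -0.0307 (Ctsk, treatment vs vehicle, day 5), -0.00766 (Dcstamp, treatment vs vehicle, day 5), 0.0678 (Tnfrsf11a, vehicle day 3 vs day 1), 0.0952 (Dcstamp, vehicle day 5 vs day 1). Leaving the low-mRNA libraries out gave -0.16 (Ctsk, treatment vs vehicle, day 3), -0.20 (Mmp9, treatment vs vehicle, day 3), -0.22 (Nfatc1, treatment vs vehicle, day 3), -0.39 (Dcstamp, treatment vs vehicle, day 3), -0.0794 (Tnfrsf11a, treatment vs vehicle, day 3), -0.057 (Irf8, treatment vs vehicle, day 3), -0.0907 (Ctsk, treatment vs vehicle, day 5), -0.064 (Dcstamp, treatment vs vehicle, day 5), 0.53 (Tnfrsf11a, vehicle day 3 vs day 1). Limma-voom on the other libraries gave -0.16 (Ctsk, treatment vs vehicle, day 3), -0.20 (Mmp9, treatment vs vehicle, day 3), -0.22 (Nfatc1, treatment vs vehicle, day 3), -0.39 (Dcstamp, treatment vs vehicle, day 3), -0.0794 (Tnfrsf11a, treatment vs vehicle, day 3), -0.0571 (Irf8, treatment vs vehicle, day 3), -0.0907 (Ctsk, treatment vs vehicle, day 5), -0.064 (Dcstamp, treatment vs vehicle, day 5), 0.54 (Tnfrsf11a, vehicle day 3 vs day 1). A low-mRNA term gave 0.35 (Tnfrsf11a, vehicle day 3 vs day 1). A term by day gave 0.49 (Tnfrsf11a, vehicle day 3 vs day 1). Single libraries left out gave ranges of -0.11 to 0.072 (Dcstamp, treatment vs vehicle, day 1), -0.19 to 2.29 (Prdx1, treatment vs vehicle, day 3), -0.21 to 1.63 (Ftl1, treatment vs vehicle, day 3), -0.46 to 0.20 (Acp5, treatment vs vehicle, day 3), -0.36 to 1.48 (Ctsk, treatment vs vehicle, day 3), -0.23 to 1.40 (Mmp9, treatment vs vehicle, day 3), -1.30 to 1.44 (Nfatc1, treatment vs vehicle, day 3), -0.66 to 1.001 (Dcstamp, treatment vs vehicle, day 3), -1.14 to 1.17 (Tnfrsf11a, treatment vs vehicle, day 3). Further ranges were -0.0635 to 0.51 (Irf8, treatment vs vehicle, day 3), -2.71 to 3.99 (Ambp, treatment vs vehicle, day 5), -1.74 to 4.53 (Ifi44l, treatment vs vehicle, day 5), -4.85 to 0.66 (Ocstamp, treatment vs vehicle, day 5), -1.25 to 0.0593 (Gpr162, treatment vs vehicle, day 5), -2.29 to 0.44 (Tmem176a, treatment vs vehicle, day 5), -1.83 to 0.0633 (Cenpf, treatment vs vehicle, day 5), -1.62 to 0.0368 (Tyms, treatment vs vehicle, day 5), -1.54 to 0.30 (Cenpe, treatment vs vehicle, day 5). Others ran over -2.88 to 0.48 (Aurka, treatment vs vehicle, day 5), -0.47 to 3.996 (P4ha2, treatment vs vehicle, day 5), -0.18 to 3.33 (Trib3, treatment vs vehicle, day 5), -0.10 to 1.72 (Manf, treatment vs vehicle, day 5), -0.22 to 1.27 (Hsp90b1, treatment vs vehicle, day 5), -0.17 to 1.10 (Calr, treatment vs vehicle, day 5), -0.17 to 1.18 (Dnajc3, treatment vs vehicle, day 5), -3.27 to 1.86 (Acp5, treatment vs vehicle, day 5), -2.33 to 2.34 (Ctsk, treatment vs vehicle, day 5). The remaining ranges were -0.77 to 1.80 (Mmp9, treatment vs vehicle, day 5), -0.49 to 0.58 (Dcstamp, treatment vs vehicle, day 5), -1.51 to 0.32 (Tnfrsf11a, treatment vs vehicle, day 5), -0.0255 to 0.93 (Irf8, treatment vs vehicle, day 5), -0.70 to 2.04 (Nfatc1, vehicle day 3 vs day 1), -1.77 to 0.53 (Tnfrsf11a, vehicle day 3 vs day 1), -3.11 to 1.07 (mt-Tt, vehicle day 5 vs day 1), -0.84 to 0.0143 (Dcstamp, vehicle day 5 vs day 1). Depth limited genes with few reads: 1 read was worth up to 1.57 normalized counts in the low-mRNA libraries and 0.757 in the deepest library.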

Other observations

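These genes were chosen after their values were seen. Spp1, which encodes the secreted matrix protein osteopontin, was an abundant transcript and was higher under treatment in 6 of 6 pairs. At day 1 the treated libraries held 166390 and 166440 normalized counts against 94676 and 76840, a log2 difference of 0.96 (SE 0.13, limma adjusted p = 0.0227 in the 8-library fit). At day 3 the values were 37328 and 13969 against 11679 and 3098 (adjusted p = 0.0670), and at day 5 they were 298080 and 31066 against 100880 and 10356 (adjusted p = 0.020). Siglec1, a sialic acid receptor of macrophages, rose under treatment by 1.26 at day 1 and 1.46 at day 5, and Tnf by 0.60 and 0.85. At day 3 Siglec1 differed by 0.87 and Tnf by 0.81 without passing. In the low-mRNA pairs Siglec1 differed by 1.79 and 1.43 and Tnf by 1.96 and 1.53 at days 3 and 5.

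Lysosome and autophagy genes were higher under treatment at day 1, with 11 of 28 rising, 1 falling and 16 not passing, and 13 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.933 with an estimated correlation). Of 18 V-ATPase subunit genes 4 rose, and 10 rose and 1 fell adjusted over the list alone at day 1 (camera adjusted p = 0.00907, adjusted p = 0.933 with an estimated correlation). At day 3 none passed, 7 fell and none rose adjusted over the list alone, and the medians were -0.23 in the first pair and 0.44 in the low-mRNA pair (camera in the 8-library fit, adjusted p = 2.21e-08, adjusted p = 0.343 with an estimated correlation). The median of all genes was higher under treatment in that low-mRNA pair too, so 0.44 there does not show a rise of this list. Over 12 libraries the V-ATPase median at day 3 was 0.09 and the list did not pass (camera adjusted p = 0.542). In vehicle cells the oxidative phosphorylation list had medians of 0.40 from day 1 to day 3 and -0.26 from day 1 to day 5 in the 8-library fit. Over 12 libraries its medians were -0.74 and -0.59, and it did not pass by camera in either comparison. The medians of all genes over 12 libraries were -0.83 and -0.59, so these values do not show a move of this list apart from all genes.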
